A study of Mus musculus with 21 samples.

How the data were processed

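The series comprises 21 samples of CD-1 mice. ERα ChIP-seq was done on vWAT with estradiol (4 libraries) and vehicle (2), and on scWAT (3), BAT (1) and Liver (2) with estradiol. H3K27ac ChIP-seq of vWAT (2 libraries with estradiol and 2 with vehicle) and RNA-seq of vWAT (3 and 2) were not used here. Groups were taken from the sample labels. Per the labels' protocols, tissue was frozen in liquid nitrogen, nuclei were isolated and sonicated, and chromatin was precipitated with the antibody sc543. The dose, route and time of the treatment and whether libraries came from separate animals are not given in the sources used here.

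Per the submitters' processing notes, the genome build was mm10 and BWA 0.7.12 and HOMER were among the tools, with no role stated. The peak caller, its cut-off, its control and how libraries were combined are not given in the sources used here. The labels of all libraries of a group point to the same peak list, so values per library were not at hand. The 5 deposited lists are in narrowPeak layout without a header. For each peak the authors deposited an enrichment ratio, relative to a background that is not stated,, a −log10 p-value and a −log10 q-value, and the position of the summit. The deposited score column was 10 times the −log10 p-value, shortened to a whole number, for 100% of peaks. The lists held 20723, 7409, 17987, 5197 and 21417 peaks (vWAT estradiol, vWAT vehicle, scWAT, BAT, Liver), of which 20715, 7400, 17971, 5193 and 21411 on chromosomes 1 to 19 and X were used. The smallest −log10 p-value was 2.64 to 2.73 in the lists, and the share with a −log10 q-value of at least 2 was 89.9%, 70.9%, 88.0%, 33.5% and 46.4%. Median peak widths were 434, 393.5, 407, 299 and 298 bp. A list from more or deeper libraries can hold more and weaker peaks, so enrichment was used within a list alone, and lists were also compared at equal size. Named peaks were ranked by enrichment, whereas rank groups, such as the 500 strongest peaks, and lists held to a given number of peaks were taken by p-value.

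Peaks of different lists were called shared when they overlapped by at least 1 bp. Shares carry 95% Wilson intervals, and medians and differences of shares carry bootstrap intervals over peaks (1000 resamples, or 500 for differences within 20 bins of enrichment). All of these cover counting error over peaks and not the spread between animals. Chance overlap was the mean of 100 redraws of each peak on its own chromosome. Coordinates are mm10 and count from 1.

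The gene table used gives symbols and spans on GRCm38.p6, the assembly of mm10, without strand, exons or sequence. Several choices fixed before the data were examined therefore had to change. Distance to a transcription start site became distance to the gene span, and a gene had a peak when a summit lay inside its span or within 25 kb of it. The promoter class became summits within 1 kb of either end of a protein-coding gene. Exons, introns and motifs were not analysed here, repeats could not be passed over when genes were named, and random gene lists were matched on 20 bins of span length in place of GC content. All 315 distinct genes of the 18 lists were found among the 21627 protein-coding genes of the table. For each list the number of members with a peak was set against 10000 random lists (one-sided), with Benjamini-Hochberg adjustment over the 18 lists within a set of peaks and a threshold of 0.05. The lists cover estrogen response, lipolysis, lipogenesis, fatty acid uptake, adipogenic factors, adipokines, insulin and glucose, brown fat, hepatocytes, cholesterol and lipoproteins, macrophages and inflammation, endothelium, stroma and matrix, mammary epithelium, mesothelium, circadian genes, nuclear receptors and cofactors, and neurons. They were fixed before the data were examined, and some genes stand in more than 1 list.

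Genes were named by a rule fixed beforehand. A peak took the nearest protein-coding gene within 50 kb. The 10 strongest estradiol-only peaks, the 5 strongest held with both treatments, the 5 strongest vehicle-only peaks and the 5 strongest of each tissue class were named, with up to 4 members of each gene list by strongest vWAT estradiol peak (BAT peak for brown fat, Liver peak for hepatocytes), and Greb1, Pgr and Esr1. Some genes that the rule gives are not reported here. Scd1, Mgll, G0s2, Lipe, Plin1, Fabp4, Pparg, Alb, Ucp1, Zic1 and Lhx8 were chosen after their values were seen. The classes of peaks found in 1 tissue disregard the vehicle list.

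Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and list tests were tested on simulated data made from the vWAT estradiol list. Of 7000 simulated peaks with 20% or 60% planted on real peaks, 20.6% and 60.3% were recovered by 1 bp overlap. Of 200 random lists of 18 genes, 2.0% were called at 0.05 without a planted effect, 58.0% when genes with a peak were drawn at odds of 3 and 82.0% at odds of 6. These simulated calls used permutation p without adjustment and fewer random lists. The rates therefore do not carry over to the adjusted calls reported below, which are stricter. Alternatives covered the overlap that counts as shared, the peaks taken, the chance model, the distance to genes and the matching of random lists. Matching on nearby peaks used 5 bins of the number of merged peak regions inside the span or within 100 kb, in place of span length. Those regions were pooled over all 5 lists and include the peaks under test, so this matching can hide part of an excess.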

Results

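Estrogen receptor alpha (ERα), the nuclear receptor that binds estradiol, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in tissues of 10-week-old CD-1 mice given estradiol or vehicle before sacrifice. The tissues were labelled vWAT, scWAT, BAT and Liver. The ERα libraries comprised 4 of vWAT with estradiol, 2 of vWAT with vehicle, 3 of scWAT, 1 of BAT and 2 of Liver with estradiol. Each of these 5 groups had 1 deposited peak list, so the lists carry no spread between animals and no test across replicates was possible. On chromosomes 1 to 19 and X the lists held 20715 peaks for vWAT with estradiol, 7400 for vWAT with vehicle, 17971 for scWAT, 5193 for BAT and 21411 for Liver. The read depth behind each list is unknown here, and the 95% Wilson intervals below cover counting error over peaks. Enrichment is the authors' own value for each peak and was compared only within a list. The labels also name H3K27ac ChIP-seq and RNA-seq of vWAT, which were not used here.

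In vWAT, where peaks were listed with and without added hormone, 16015 of 20715 estradiol peaks had no counterpart in the vehicle list, and many of the strongest of these lay within genes or some distance from them rather than at gene ends. Greb1, a classical estrogen target, had 4 estradiol peaks and 1 vehicle peak inside its span or within 25 kb of it, with an enrichment of up to 16.9 with estradiol. Pgr, which encodes the progesterone receptor, had 4 and 1, with up to 15.3. Esr1, the gene of ERα itself, had 15 estradiol peaks, 14 of them absent from the vehicle list, against 2 vehicle peaks. Its strongest estradiol peak (11.1) was held with vehicle. The gene spans 394 kb, and a longer span can hold more peaks by its length alone. Of the 7400 vehicle peaks 2677 were absent from the estradiol list. Both counts of unshared peaks were taken between lists of different length, so their difference can follow list length. With both lists held to 7400 peaks, 4456 and 4432 were unshared. At equal size about the same overlaps are counted from either side, so this likeness does not decide the matter.

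The estradiol-only peak with the largest enrichment (21.5) lay on chromosome 10 at 79865551 to 79866176 (mm10), inside the span of Plppr3 and within 25 kb of Cfd, which encodes the adipokine adipsin. A peak on chromosome 13 at 53346306 to 53346933 lay inside Sptlc1, which encodes a subunit of the enzyme that starts sphingolipid synthesis, 13.9 kb from the nearer end of the gene, with an enrichment of 19.4. Peaks inside Wdr27 (18.3), Itpk1 (18.1), an inositol phosphate kinase gene, and Zfp469 (17.9) were likewise estradiol-only. The remaining peaks of the 10 strongest lay outside gene spans, 19.9 kb from Rnase10 (20.9), 37.8 kb from Gm46240 (20.6), 35.9 kb from Efcab1 (18.5), 3.68 kb from Tmem144 (18.2) and 9.80 kb from Zcchc10 (17.9). All 10 were also found in the scWAT list and none in the Liver list. The gene table used gives spans without exons or strand, so exonic, intronic and promoter positions were not assigned.

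The strongest peaks held with both treatments were present in all 5 lists. The first lay at 103648891 to 103649479 on chromosome 6 inside Chl1 (25.1), 83.8 kb from its nearer end, and the next 14.95 kb from Dpy19l2 (24.6). The others lay within 1 kb of an end of Vti1a (23.3), a vesicle fusion gene, Rexo4 (23.1) and Banf1 (22.9), which encodes a chromatin-binding protein of the nuclear envelope. Repeats could not be passed over, so whether these peaks reflect receptor binding was not tested. The strongest vehicle-only peaks were weaker within their own list, at an enrichment of 8.19 inside Slc24a3, 7.76 near Setd5, 7.73 near Slc25a28, a mitochondrial iron carrier gene, 7.60 near Tmem45a and 7.59 near Arhgap5. Of these 5 peaks, those near Setd5, Slc25a28 and Arhgap5 were found in the Liver list.

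Of the estradiol peaks, 22.7% (22.1 to 23.3) were found in the vehicle list, and of the vehicle peaks 63.8% (62.7 to 64.9) were found in the estradiol list. Positions redrawn on the same chromosome gave 0.277% and 0.781%. Within the estradiol list the median enrichment was 6.70 (bootstrap interval 6.55 to 6.90) for peaks held with both treatments and 4.59 (4.59 to 4.62) for estradiol-only peaks. Within the vehicle list it was 5.75 (5.65 to 5.87) for shared and 4.23 (4.16 to 4.24) for vehicle-only peaks. The share found in the other list fell with rank in both lists. Of the 500 strongest vehicle peaks, 100% were found with estradiol, whereas of the 500 strongest estradiol peaks 77.0% (73.1 to 80.5) were found with vehicle. These shares were looked up in lists of different length, so their difference can follow list length. With both lists held to 7400 peaks, about the same overlaps are counted from either side, and the shares were 39.8% and 40.1%.

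**Figure D1:**
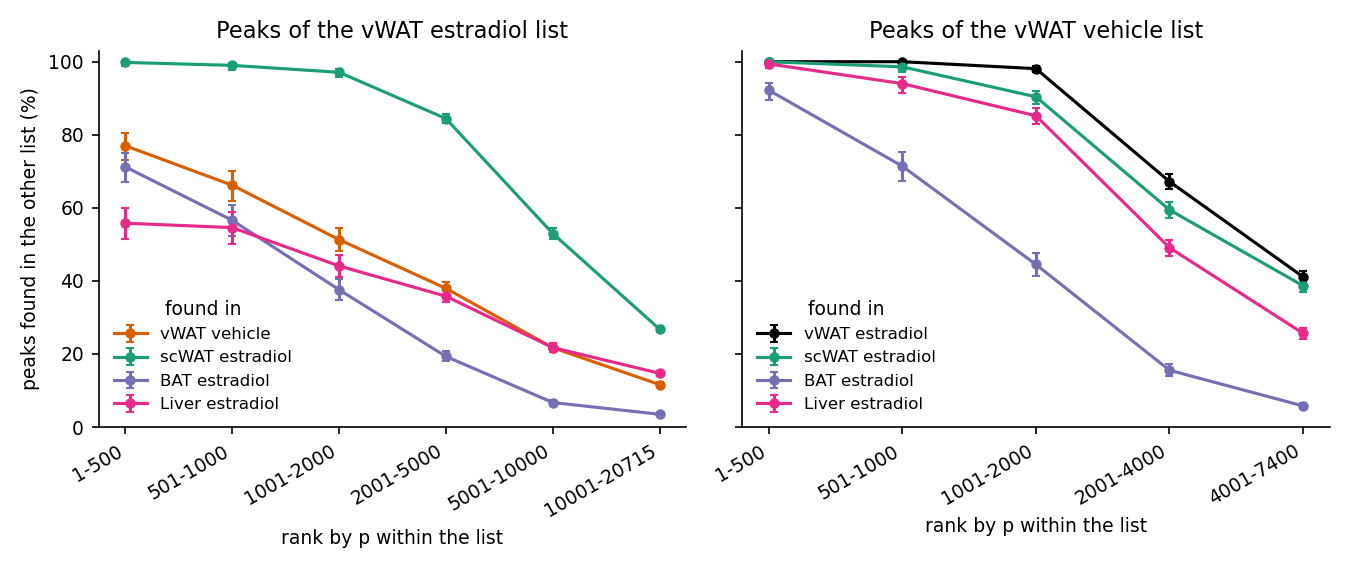
Share of peaks of the vWAT estradiol list (left) and of the vWAT vehicle list (right) found in each other list, in percent, against the rank of the peak by p within its list; points are shares and bars 95% Wilson intervals. Of the 500 strongest estradiol peaks 99.8% were found in scWAT and 77.0% with vehicle, and of the 500 strongest vehicle peaks 100% were found with estradiol.

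Peaks held with both treatments lay at gene ends and estradiol-only peaks mostly did not. Summits within 1 kb of either end of a protein-coding gene made up 62.4% (61.1 to 63.8) of the shared class, 12.8% (12.2 to 13.3) of the estradiol-only class and 33.5% (31.7 to 35.3) of the vehicle-only class, against 3.12% to 3.27% of redrawn positions. Among the 1433 peaks of the vWAT estradiol list that were found in all the other lists the share was 81.3% (79.2 to 83.2). A further 44.3% of estradiol-only summits lay inside gene spans away from their ends, against 38.8% of redrawn positions. Only 12.1% lay over 100 kb from any protein-coding gene, against 27.7% of redrawn positions. Over whole lists the share at gene ends was 24.0% for vWAT with estradiol, 52.0% with vehicle, 29.7% for scWAT, 34.4% for BAT and 25.2% for Liver. The estradiol-only share was 5.64% when each list was held to its 5193 strongest peaks and 24.9% within 5 kb, below the shared class in each case (69.6% and 71.7%).

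**Figure D2:**
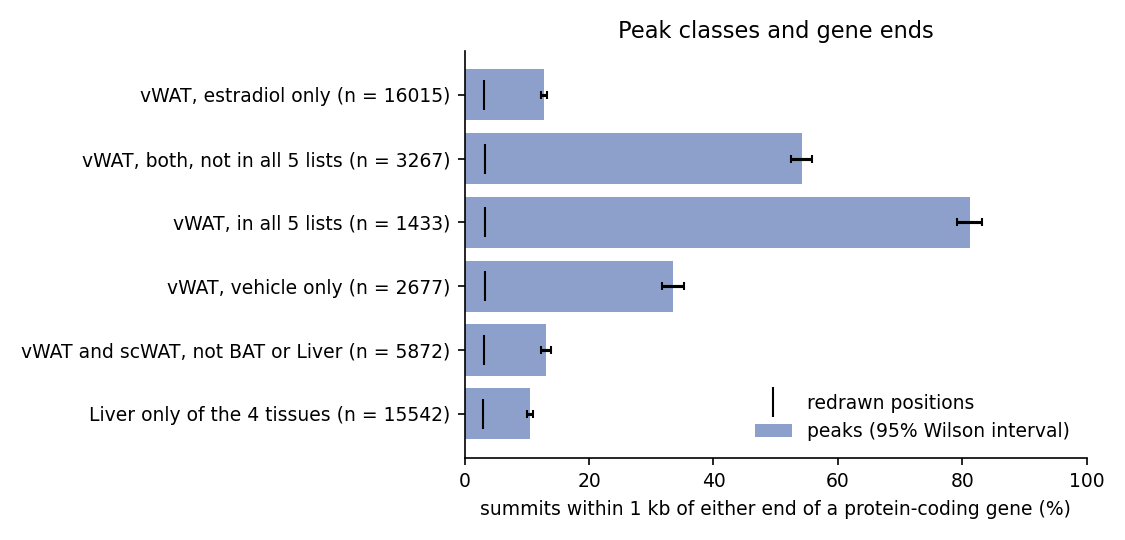
Percentage of summits within 1 kb of either end of a protein-coding gene for 6 classes of peaks; bars are shares with 95% Wilson intervals and vertical ticks the mean of redrawn positions. The share rises from 12.8% of estradiol-only peaks to 81.3% of vWAT peaks found in all 5 lists.

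Genes of fat storage and fat release carried estradiol-only peaks. Against random genes matched on nearby peaks their counts did not pass the threshold (adjusted permutation p = 0.0558 for lipogenesis and 0.1571 for lipolysis). That matching counts the tested peaks themselves, so it can hide part of an excess. The counts did not pass with peaks counted up to 100 kb away either (0.1264 and 0.1423). In both tests all 18 lipogenesis genes had a peak, the most possible, so no larger count could have lowered their p. All 18 lipogenesis genes had an estradiol-only peak inside the span or within 25 kb, against a median of 10 in random gene lists matched on span length (one-sided permutation test, p = 0.0001, the smallest the draws can give; Benjamini-Hochberg adjusted p = 0.0018). The count was 8 of 18 at 5193 peaks per list and 11 of 18 in the stronger part of each list, both past the threshold (adjusted permutation p = 0.0072 and 0.0311). The strongest vWAT peaks of this list, near Fasn, fatty acid synthase (18.6), Srebf1, a transcription factor of lipid synthesis (14.5), Gpam (12.5) and Acacb (11.1), were also held with vehicle, and the estradiol-only peaks beside them were weaker, up to 9.51 near Srebf1 and 4.66 near Fasn. Scd1, stearoyl-CoA desaturase, had 3 estradiol-only peaks (up to 8.73) and no vehicle peak. Of 18 lipolysis genes 15 had an estradiol-only peak (random median 8, adjusted permutation p = 0.0048), and 5 of the 18 had any vehicle peak (random median 8). With each list held to its 5193 strongest peaks, 4 of the 18 had an estradiol-only peak (adjusted permutation p = 0.245). Pde3b, a phosphodiesterase of insulin action, had an estradiol-only peak of 9.41, and Mgll, monoglyceride lipase (8.35), and G0s2, an inhibitor of adipose triglyceride lipase (8.29), had 3 each without a vehicle peak. Lipe, hormone-sensitive lipase, and Plin1, which coats the lipid droplet, had 2 each. The stronger peaks near Prkar2b, a regulatory subunit of protein kinase A (15.8), Plin2 (13.9) and Pnpla2, adipose triglyceride lipase (10.00), were also held with vehicle.

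Other adipocyte, insulin, matrix and clock genes also carried estradiol-only peaks. None of these calls held against random genes matched on nearby peaks, tested ones included (adjusted permutation p 0.1374 to 0.482), or with peaks counted up to 100 kb away (0.1264 to 0.299). At the same number of peaks the counts were 8 of 18 adipogenic factors and 7 of 18 stroma and matrix genes, still past the threshold (adjusted permutation p = 0.0187 and 0.0072), and the insulin and glucose (5 of 18, adjusted permutation p = 0.2686) and circadian calls (3 of 16, adjusted permutation p = 0.5003) were lost. Within 5 kb the stroma and matrix call was lost (8 of 18, adjusted permutation p = 0.3171). Of 14 fatty acid uptake genes 11 had an estradiol-only peak (random median 6, adjusted permutation p = 0.0345), among them Lrp1 (11.3), Cav1 and Cav2, which share a peak (10.9), and Fabp4, the adipocyte fatty acid binding protein (10.8), whereas the strongest peak of the list, near Slc27a4 (15.5), was also held with vehicle. Of 18 adipogenic factors 16 had one (random median 10, adjusted permutation p = 0.0036). Their strongest peaks, near Zfp423, a preadipocyte transcription factor (16.5), Stat5a and Stat5b, which share a peak (16.3), and Nr3c1, the glucocorticoid receptor (10.8), were also held with vehicle, and the strongest estradiol-only peak of the list lay near Stat5b (13.6). Pparg, the main adipogenic nuclear receptor, had 6 estradiol peaks, 5 of them estradiol-only. Of 18 insulin and glucose genes 16 had one (random median 10, adjusted permutation p = 0.0081), led by Pik3r1 (10.7), Pck1 (10.4), Hk2 (9.45) and Insr, the insulin receptor (9.17). Of 18 stroma and matrix genes 15 had one (random median 9, adjusted permutation p = 0.0087), led by Dcn, decorin (17.7), Col6a3 (14.5) and Cd34 (14.1), while the next strongest peak, near Timp1 (8.93), was also held with vehicle. Of 16 circadian genes 14 had one (random median 8, adjusted permutation p = 0.0087), led by Per2 (11.0), while stronger peaks near Arntl (18.1) and Dbp (11.7) were also held with vehicle.

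The other lists did not pass the threshold for estradiol-only peaks. Of 26 estrogen response genes 19 had one (random median 14, adjusted permutation p = 0.0544), with the strongest near Greb1 (16.9) and Pgr (15.3), and the peaks near Xbp1 (19.4) and Igfbp4 (15.5) were also held with vehicle. Of 16 adipokine genes 10 had one (adjusted permutation p = 0.145). The adipokine peaks near Cfd (21.5) and Vegfa (15.4) and all 4 peaks near Lep, the gene of leptin (12.7), were estradiol-only, and a peak near Fgf21 (15.2) was not. The counts were 12 of 20 brown fat genes, 7 of 10 mesothelium genes, 9 of 17 cholesterol and lipoprotein genes, 12 of 18 nuclear receptor and cofactor genes, 8 of 15 endothelial genes, 8 of 18 mammary epithelium genes, 6 of 16 macrophage and inflammation genes, 9 of 26 hepatocyte genes and 7 of 20 neuronal genes, with adjusted permutation p from 0.374 to 0.984. Over all peaks of the vWAT estradiol list the lipogenesis (18 of 18, adjusted permutation p = 0.009) and adipogenic factor lists (18 of 18, adjusted permutation p = 0.0072) passed. Over the vehicle list the adipogenic factors (14 of 18, adjusted permutation p = 0.0378), the circadian genes (13 of 16, adjusted permutation p = 0.0486) and the nuclear receptors and cofactors (15 of 18, adjusted permutation p = 0.0324) passed. For peaks held with both treatments, 15 of 18 nuclear receptor and cofactor genes had one (random median 6, adjusted permutation p = 0.0018), with peaks near Nrip1, a corepressor (14.6), and Nr1h3, a liver X receptor (13.9). These p-values describe the peak lists, as genes are not replicates and neighbouring genes can share a peak that counts for each of them. Matching on nearby peaks ended the call for nuclear receptors and cofactors held with both treatments (adjusted permutation p = 0.0792). It also ended the lipogenesis (0.7337) and adipogenic factor calls (0.216) over all vWAT estradiol peaks, and both were lost at 100 kb (0.225 each). All 18 members of these 2 lists had a peak in both tests, the most possible, so no larger count could have lowered p. The vehicle calls were not run under these alternatives.

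**Figure D3:**
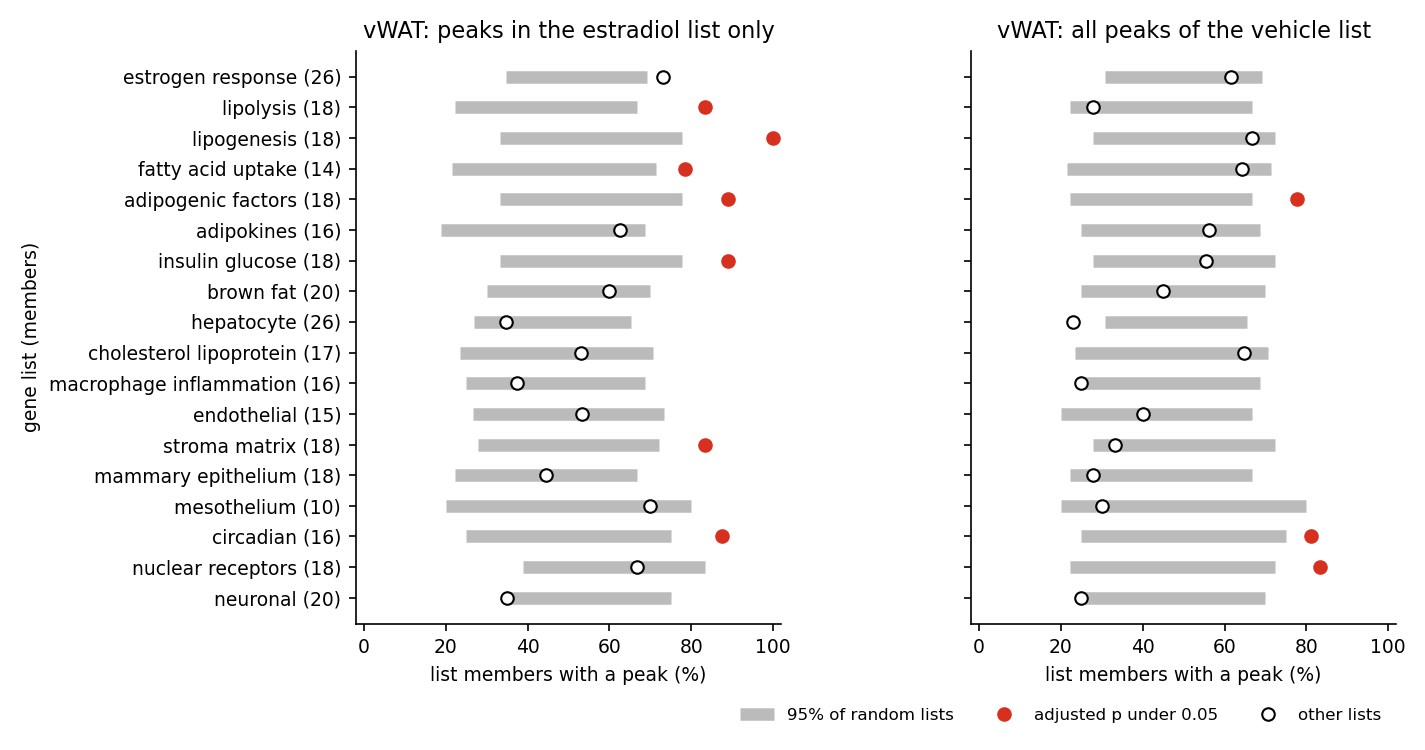
Percentage of the members of each of 18 gene lists with a peak inside the gene span or within 25 kb, for peaks in the vWAT estradiol list alone (left) and for all vWAT vehicle peaks (right); grey bars span the central 95% of random lists matched on span length, and filled points have an adjusted p under 0.05. An estradiol-only peak was held by all 18 lipogenesis and 15 of 18 lipolysis genes. A vehicle peak was held by 12 of 18 and 5 of 18, both inside the central 95% of random lists.

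Between tissues with estradiol, vWAT and scWAT shared the most peaks, 48.4% (47.7 to 49.0) of the vWAT list and 56.0% (55.3 to 56.7) of the scWAT list. Of the vWAT peaks, 22.8% (22.3 to 23.4) were found in Liver and 11.1% (10.7 to 11.6) in BAT, against 0.713% and 0.177% for redrawn positions. With each list held to its 5193 strongest peaks, 66.2% of vWAT estradiol peaks were found in scWAT, 43.7% in the vehicle list of the same tissue, 33.6% in Liver and 31.1% in BAT. The share in scWAT exceeded that in the vWAT vehicle list by 22.5 percentage points (bootstrap interval over peaks 20.9 to 24.2). At this size the vehicle peaks of vWAT were found in Liver (46.1%) more often than in the vWAT estradiol list (43.8%), by 2.23 points (0.904 to 3.66), but the direction turned over all peaks, of which 49.6% were found in Liver and 63.8% in the vWAT estradiol list. The BAT share depended on the number of peaks taken, since it was 11.1% over all peaks and 31.1% at the same size. Without the peaks common to all lists it was 4.48%, and the Liver share was 13.2% when summits had to lie within 100 bp of each other.

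**Figure D4:**
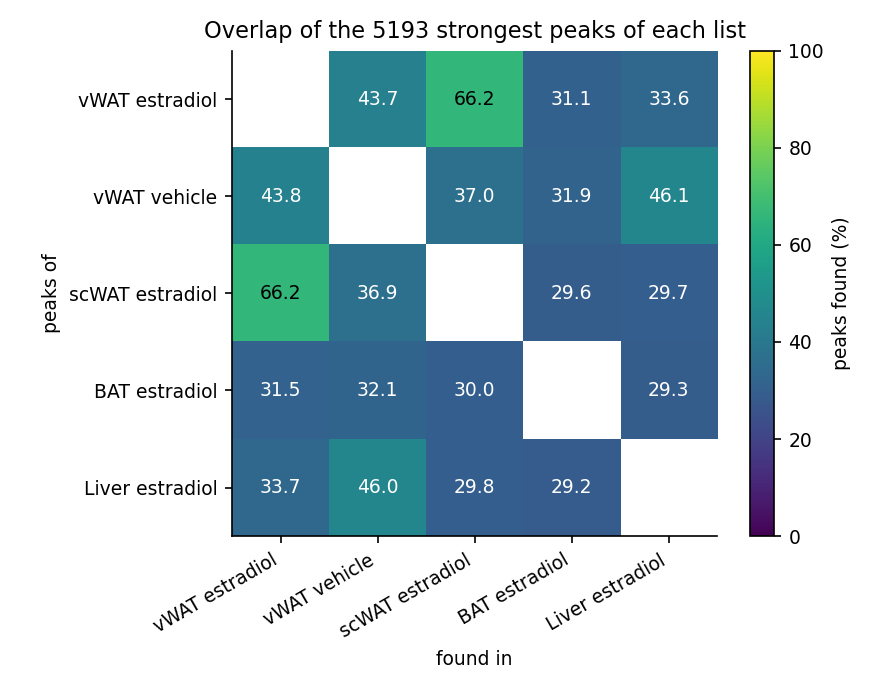
Percentage of the 5193 strongest peaks of each list (rows) found among the 5193 strongest of each other list (columns), on a colour scale from 0 to 100. The pair of vWAT and scWAT with estradiol reached 66.2%, and the pair of vWAT with vehicle and Liver with estradiol 46.1%.

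The tissue classes that follow compare the estradiol lists and disregard the vehicle list. Peaks of vWAT and scWAT that were absent from BAT and Liver made up 28.3% (27.7 to 29.0) of the vWAT list. The strongest lay near Rnase10 (20.9), inside Sptlc1 (19.4), inside Stk39, a kinase gene of ion transport control (19.3), inside Ampd3, an AMP deaminase gene (18.98), and near Efcab1 (18.5). Those of Stk39 and Ampd3 also had a vehicle peak. Another 45.6% (44.9 to 46.3) of the vWAT list was found in no other tissue. Among the strongest of these were peaks at 63295873 to 63296559 on chromosome 14, 24.5 kb from Gata4, a GATA transcription factor gene (17.4), 26.8 kb from Tagap (15.9), 5.87 kb from Treml1 (15.8) and inside Hunk (14.8). The peaks near these 4 genes had no vehicle counterpart. In the scWAT list 37.9% (37.2 to 38.6) of peaks were found in no other tissue, with the strongest inside Nubpl (14.4), Ccdc85c (14.2), Ablim1 (14.2) and Gatb (13.99) and 39.5 kb from Dnttip2 (13.1). Peaks of the vWAT list found in all 4 tissues made up 7.52% (7.17 to 7.89), with the strongest at Chl1, Dpy19l2, Vti1a, Rexo4 and Banf1 as above, and 92.0% of them also had a vehicle peak.

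In Liver, where 46.4% of all peaks had a −log10 q-value of at least 2, 72.6% (72.0 to 73.2) of peaks were found in no other tissue. Within the list these were weak, with a median enrichment of 3.33 against 3.91 over all Liver peaks. The strongest of these lay 16.1 kb from Gm6124 (12.05), inside Tcf7l2, a transcription factor gene of Wnt signalling (11.3), 4.18 kb from Cux2, a homeobox gene (10.0), at an end of Purg (9.66) and inside Gm33851 (9.36). Those of Cux2 and Gm33851 also had a peak in the vWAT vehicle list. Of 26 hepatocyte genes 21 had a Liver peak (random median 18, adjusted permutation p = 0.384) and 12 a vWAT estradiol peak (random median 17, adjusted permutation p = 0.992), and the difference between tissues was not tested. Alb, which encodes albumin, had 4 Liver peaks and Tat, tyrosine aminotransferase, 5, and neither had a peak in the other lists. Among the strongest Liver peaks of this list were those near F2, Foxa3 and Tat, of which those of F2 (22.1) and Foxa3 (11.9) lay outside the gene spans, in regions with peaks in every list. No gene list passed in Liver, where the smallest adjusted permutation p was 0.2295 for the adipogenic factors and for the cholesterol and lipoprotein genes.

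In BAT, where 33.5% of all peaks had a −log10 q-value of at least 2, 48.5% (47.2 to 49.9) of peaks were found in no other tissue. Their median enrichment was 4.14, against 4.32 over all BAT peaks. The strongest of these lay 25.3 kb from Pwwp2b (7.59), 12.8 kb from Sdr39u1 (7.51) and 10.5 kb from Vmn1r15 (7.20). Next were peaks inside Edil3 (6.76) and 11.7 kb from Tmsb15a on chromosome X (6.76). Of 20 brown fat genes 13 had a BAT peak (random median 6, adjusted permutation p = 0.0558), and no list passed in BAT. The strongest BAT peaks of the list lay near Esrra, estrogen-related receptor alpha (18.03), Cox7a1, a cytochrome c oxidase subunit (11.1), Prdm16, a brown fat transcription factor (6.63), and Esrrg (5.76). Those of Esrra and Cox7a1 lay in regions with peaks in every list. Those of Prdm16 and Esrrg overlapped vWAT estradiol peaks that were also found in scWAT. Ucp1, which encodes the uncoupling protein of brown fat, had no BAT peak, 2 vWAT estradiol peaks and 1 scWAT peak (9.39). Zic1 and Lhx8, transcription factor genes used as brown fat markers, had 1 BAT peak each and no peak in the other lists. Neither of these peaks exceeded the median enrichment of the BAT list (4.32), which came from 1 library. In scWAT the adipogenic factors (17 of 18, adjusted permutation p = 0.0144) and all 16 circadian genes (adjusted permutation p = 0.0144) passed, in tests not repeated under other settings.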

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

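The tests on collapsed repeats, on gene ends open in every tissue and on the libraries behind the vehicle list, the BAT comparison among them, were chosen after the result was seen. The scWAT list held 14 peaks on chromosome Y, used only where chromosomes M and Y were kept as an alternative, against 7 in the vWAT vehicle list. They lay between 90719666 and 90829966 on that chromosome.

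Peaks common to all 5 lists, vehicle included, were strong within the lists and mostly lay near gene ends. Peak strength alone would find peaks of equal enrichment in Liver equally often wherever they lie, but at equal enrichment in the vWAT estradiol list those near gene ends were found in Liver more often by 50.6 percentage points (95% bootstrap interval 49.2 to 52.0). Reads misplaced from collapsed repeats were predicted not to gather at gene ends, where 81.3% of the common peaks lay against 3.33% of redrawn positions. That share is part of the pattern to be explained, and repeats were not examined, so it cannot decide on this explanation. Background at strongly transcribed genes would mark the hepatocyte genes in Liver, but 7 of 26 had a Liver summit within 1 kb of an end (random median 8, central 95% of random lists 4 to 13). Genes strongly transcribed in every tissue were not tested, so these counts speak of hepatocyte genes in Liver alone. Background at the ends of genes open in every tissue and receptor binding there cannot be told apart for the 1461 genes with a common peak within 1 kb of an end, because no library made without the antibody was used here.

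More peaks were listed with estradiol than with vehicle in vWAT, and the number of libraries and the treatment cannot be told apart as its source, since 4 libraries stand behind the first list and 2 behind the other. At equal enrichment, estradiol peaks near gene ends were found with vehicle more often than others by 44.2 percentage points (42.8 to 45.7). Fewer libraries that missed peaks of equal enrichment equally often wherever they lie would give no such difference. The difference was larger for Liver (50.6 points, 49.2 to 52.0), a list also made with estradiol, so it does not single out the treatment. Of the 500 strongest estradiol peaks, 71.2% (67.1 to 74.996) were found in the BAT list, from 1 library, and 77.0% (73.1 to 80.5) in the vehicle list, with intervals that overlap. The 37.4% of the estradiol-only peaks among these that were found in BAT decide nothing, as the peaks were picked for their absence with vehicle. A response of the receptor to estradiol stays open as untested, as do differences in precipitation efficiency between the groups.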

How the results depend on the processing

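The −log10 q limit, leaving out peaks common to all 5 lists and counting peaks within 25 kb of either gene end alone were chosen after seeing the data. No paired analysis was possible because each group has 1 peak list, so no replicate could be left out either. The motif alternatives (narrower and wider windows, farther flanks, 0 and 2 mismatches, the stronger part of each list, the same number of peaks) and matching on GC content were not run, since no genome sequence was used, and chance windows at transcription start sites gave way to local shifts. Read depth was unknown, which limits every comparison of list sizes.

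Values for vehicle peaks found with estradiol (63.8%), estradiol peaks found with vehicle (22.7%), and vWAT peaks found in scWAT (48.4%), BAT (11.1%) and Liver (22.8%) were, in that order, 43.0%, 15.4%, 34.2%, 7.23% and 13.16% with summits within 100 bp, 52%, 18.6%, 41.4%, 7.48% and 16.9% with reciprocal overlap of 50%, 73.5%, 26.3%, 55.7%, 13.17% and 27.8% in the stronger part of each list by median p, 40.1%, 39.8%, 66.2%, 31.1% and 33.6% with the same number of peaks (7400 for the first pair, 5193 for the others), 91.4%, 27.6%, 59.1%, 6.61% and 21.2% at a −log10 p of 10 or more, and 72.8%, 20.5%, 49.2%, 6.87% and 19.9% at a −log10 q of 2 or more. Without the common peaks the tissue shares were 44.4%, 4.48% and 17.03%. Keeping chromosomes M and Y left these shares within their intervals. The 16015 estradiol-only peaks became 7638 in the stronger part, 4456 at the same number (7400) and 5168 at a −log10 p of 10 or more, where fewer peaks were taken. Local shifts raised chance overlap from 0.781% to 1.66% (vehicle with estradiol) and from 0.671% to 1.25% (vWAT with scWAT).

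Shares near gene ends for all estradiol, estradiol-only and shared vWAT peaks (24.0%, 12.8% and 62.4%) were 35.5%, 24.9% and 71.7% within 5 kb, 29.3%, 18.03% and 67.6% with all annotated genes, 27.4%, 11.2% and 72.8% in the stronger part, and 33.5%, 5.64% and 69.6% at the same number (5193), with the shared class above the estradiol-only class each time.

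The number of gene lists past the threshold over all vWAT estradiol peaks (2) was 4 within 5 kb, 0 within 100 kb, 6 with no matching of random lists, 0 with matching on the number of peaks within 100 kb, 6 in the stronger part, 4 at the same number and 5 within 25 kb of either end only. For estradiol-only peaks (7) it was 0 within 100 kb and 0 with matching on the number of peaks, and 6 to 9 under the other alternatives. For shared peaks (1) it was 2 within 100 kb, 0 with matching on the number of peaks and 2 in the stronger part. Of 7 alternatives, the lipogenesis, fatty acid uptake and adipogenic calls for estradiol-only peaks passed under 5 and the lipolysis, insulin, stroma and circadian calls under 4 (adjusted p from 0.0009 to 0.5003). Except where fewer peaks were taken, the cause was not tested. Where all members of a list already had a peak, as for lipogenesis at 100 kb, no larger count was possible.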

Other observations

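All tests in this part were chosen after the result was seen or parts of it were, on gene lists fixed before. Classes of 1 tissue compare the estradiol lists alone. Peaks found in Liver and in no other tissue gathered at genes of hepatocytes against random genes of like span. They did not against genes matched on nearby peaks, tested ones included (adjusted permutation p = 0.1242). Of 26 hepatocyte genes 20 had such a Liver-only peak inside the span or within 25 kb (random median 12, one-sided adjusted permutation p = 0.0324 over 18 lists), among them Alb, Tat, Cps1 and the fibrinogen genes Fga, Fgb and Fgg. The fibrinogen genes are neighbours, and Fga and Fgg share their strongest Liver peak. A shared peak counts for each gene, and the random lists do not keep neighbours together. Of 17 cholesterol and lipoprotein genes 14 had one (random median 9, adjusted permutation p = 0.0558), as had 13 of 15 endothelial genes (random median 8, adjusted permutation p = 0.0558). Peaks found in vWAT and in no other tissue gathered at adipogenic factors (17 of 18, random median 8, adjusted permutation p = 0.0018), lipolysis genes (12 of 18, adjusted permutation p = 0.0153), lipogenesis genes (13 of 18, adjusted permutation p = 0.0153), adipokines (10 of 16, adjusted permutation p = 0.0153), stroma and matrix genes (12 of 18, adjusted permutation p = 0.0212), insulin and glucose genes (13 of 18, adjusted permutation p = 0.0237) and fatty acid uptake genes (9 of 14, adjusted permutation p = 0.0319). Peaks found in scWAT and in no other tissue gathered at circadian genes (12 of 16, adjusted permutation p = 0.0216), adipokines (10 of 16, adjusted permutation p = 0.0405) and adipogenic factors (12 of 18, adjusted permutation p = 0.0492). No list passed for BAT-only peaks, where the smallest adjusted permutation p was 0.1332 for the adipogenic factors (8 of 18). With random genes matched on 5 bins of the number of peaks within 100 kb, the vWAT call for adipogenic factors held (adjusted permutation p = 0.0036) and the other calls did not (0.1134 to 0.7949). Span length was not matched here, and genes within a bin can differ in peak number, which may matter for long genes. Differences between tissues were not tested.

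Some genes held many estradiol-only vWAT peaks. Arhgap26 had 31 inside its span or within 25 kb, Lrmda 25, Prkce, a protein kinase C gene, 21, Tshz2 20 and Trabd2b, which encodes a protease that acts on Wnt proteins, 19. Adam12, a metalloprotease gene of mesenchymal cells, had 18 and no vehicle peak, and Slit3, an axon guidance gene, had 17 and no Liver peak. These genes span 208 kb or more, and a longer span can hold more peaks by its length alone. Among genes under 50 kb, Htra3 had 10, Tgm2, transglutaminase 2, 9, Capn9 8 and Ctsb, cathepsin B, 8. Ctsb and Ccdc80, a gene of the adipose matrix (7), had no vehicle or Liver peak. These genes were ranked by their counts after the values were seen.

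The Liver and BAT lists held larger shares of peaks on chromosome X (3.19% and 2.48%) than the vWAT estradiol (1.48%), vWAT vehicle (1.95%) and scWAT (1.22%) lists. A candidate explanation is that their weak peaks fall like background over the genome, of which X made up 6.56% of the covered length. In Liver the X share was 4.24% (3.88 to 4.62) among peaks with a −log10 q-value under 2 and 1.98% (1.73 to 2.27) among the others. In BAT it was 2.95% (2.44 to 3.57) and 1.55% (1.07 to 2.25). Both differences run the way that explanation predicts, but the X shares of the weak peaks stayed below 6.56%. Of the weak peaks 11.8% in Liver and 25.6% in BAT lay within 1 kb of a gene end. Redrawn positions of the whole lists gave 3.10% and 3.18%, so the explanation can cover the weak peaks only in part. The weak peaks of the other lists held no such excess on X, with 1.49% against 1.48% in vWAT with estradiol, 1.809% against 2.002% with vehicle and 1.34% against 1.20% in scWAT.

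As the strongest vWAT-only peak lay near Gata4, the hypothesis that vWAT-only peaks gather at genes of mesothelium, the lining of visceral organs, was put to a test. Of 10 mesothelium genes 5 had a vWAT-only peak (random median 4, central 95% of random lists 1 to 7, adjusted permutation p = 0.4824), so this small list does not decide the matter.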
